A study of Escherichia coli with 6 samples.

How the data were processed

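Total RNA of Escherichia coli was measured on 6 single-channel microarrays, 3 of the parental strain MDS42 and 3 of its recA deletion mutant. Per the labels' protocols, both strains grew in a modified M9 minimal medium at 34 °C from a starting OD600 of 0.1 and were harvested at an OD600 of about 1. RNA with an integrity number of at least 8.4 was used, and 100 ng of it was labelled with Cy3. The sample labels call the harvest mid-exponential and the series design calls it early exponential, a difference that these sources do not settle. The series design states that the 3 replicates of each strain came from independent cultures. The groups were taken from the sample titles.

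All 6 arrays lay on 1 slide and shared 1 scan session, per the file headers. The 3 parental arrays and deletion array 1 lay in row 1 of the slide, and deletion arrays 2 and 3 in row 2. The scanner files hold intensity values from Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes: processed signals, from which the authors' software had subtracted background within each array and which were not scaled between arrays. They cover 59948 numbered probes and 50 catalogue probes with 34 spots each, and pair no probe with a gene name or sequence. The deposited value table holds 1 log10 value per gene and array for 4469 gene symbols. Its 6 columns contain the same sorted values, with a largest difference of 0, so the authors had quantile-normalized it. Its scale was inferred by setting its quantiles against those of the log10, log2 and natural log processed signals: the median was 2.17 in every column, and the log10 medians of the scanner signals ran from 1.88 to 2.08. The values were not centred per gene. How probes were summarised to genes, and in which order the steps were taken, is not given in the sources used here. Quantile normalization gives every array the same distribution, so a shift of the whole transcriptome cannot be seen in this table.

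The planned gene values were to come from the scanner files. Because those files name no genes, the gene analysis used the deposited log10 table, multiplied by log2(10), and the scanner signals were analysed per numbered probe. A gene counted as dim on an array below a log10 signal of 1.34, the mean over the arrays of the lowest signal among probes well above background, equal to a signal of 22.0. This gene-level filter was set after the files were seen. Genes at or above the limit on all 3 arrays of at least 1 strain were tested. Where a strain was dim on all its arrays, the fold is given as a bound, the mean of the brighter strain against the limit. The 6 arrays limit the precision: the median standard error (SE) of a log2 difference was 0.08.

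Differences are log2 values of the deletion strain minus the parental strain, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 6 arrays with strain as the only term. Tests were two-sided with Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05. A set of 33 gene lists, together with the rule for naming genes, had been fixed before the data were examined. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Of the 986 list names, 980 were found in the table, 53 of them under an older or newer symbol. Symbols were matched through RefSeq's table for assembly ASM584v2 of strain MG1655: 3679 were current symbols, 673 matched a synonym and 117 matched no gene. That table was used only for names and neighbours, since no build is named in the sources used here.

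The naming rule took recA, the 12 largest rises and the 12 largest falls past the threshold, up to 4 called members of each list by size of change, and 6 SOS genes whatever their values. Not every gene so taken is printed below. Those left out include rpsT, prfA, infA, sdhC, fepD, mutT, xseA, tyrA and trpE, whose calls were lost with slide row as a block. The genes asr, cbl, yfiA, udp, aceB, nrdE, nrdF, nrdG, rhlE, rbfA, gltL and glgX were named after their values had been seen.

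For the probe analysis, outlier-flagged spots were left out, spots of one probe were averaged, log2 processed signals were centred on each array's 75th percentile, and probes well above background on all arrays of at least 1 strain were kept. The alternatives were normexp with an offset of 50, quantile normalization, median centring, cyclic loess, scaling on 6 spike-in probes, other filters on dim probes and genes, the replicate number or the slide row as a block, trend and robust variance, a plain t-test, a minimum log2 difference of 1, and each array left out in turn. The files hold no mean spot signal, so normexp used the median. The gene analysis was tested on simulated data for the comparison of the strains, with 3140 genes, of which 50 at each size were changed. It recovered 26% of the changes of 0.25 on the log2 scale, 94% of 0.5, 98% of 1 and 100% of 2. Of its 170 calls 11 were false, and 0 of 25 unchanged lists were called. In the data 31.7% of tested genes were called, a far larger share than was changed in the simulation. The adjustment for multiple tests then acts differently, so the recovery of small changes may not carry over. The noise was drawn independently for each gene, and the unchanged lists held random genes. The simulation therefore cannot show how often camera falsely calls lists of correlated genes, where the estimated correlation reached 0.42.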

Results

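The study compared the transcriptome of Escherichia coli MDS42, a reduced-genome derivative of strain K-12, with that of the same strain lacking recA. RecA is the recombinase of homologous recombination, and its filaments on single-stranded DNA trigger self-cleavage of LexA, the repressor of the SOS regulon. The series title places the comparison within work on how loss of recA alters sensitivity to chemical compounds; no compound is named for these cultures. Each strain was measured on 3 arrays of independent cultures grown in modified M9 medium. Between 62.4% and 63.6% of probes were well above background on the parental arrays, against 63.9%, 69.5% and 65.6% on deletion arrays 1, 2 and 3. The median processed signal lay between 76.5 and 121 on the 6 arrays, and 0 spots were saturated. Of 4469 genes, 3140 were tested, 1182 were dim on all arrays of both strains, and the other 147 met neither condition.

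The deleted gene was checked first. The recA signal was 10.89 ± 0.05 on the log2 scale in the parental strain (SD, n = 3) and 2.67 ± 0.29 in the deletion strain (SD, n = 3), where it was dim on all 3 arrays. This was at least 86.1-fold lower in the deletion strain (limma adjusted p = 7.86e-09). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 arrays against 3 allow.

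Nitrogen assimilation genes made up 6 and SOS genes 3 of the 12 largest falls besides recA, and heat shock genes 3 of the 12 largest rises. In all, 996 genes (31.7% of those tested) passed the limma threshold, 494 higher and 502 lower in the deletion strain. Most changes were small, with a median size of 0.37 on the log2 scale, and 30 genes changed by at least 1, 15 in each direction. Besides recA, the largest fall was that of glnK, a PII-type nitrogen signalling protein (-2.94, SE 0.14, adjusted p = 1.05e-05), and the largest rise that of ibpB, a small heat shock protein (1.95, SE 0.09, adjusted p = 8.76e-06). Outside the lists described below, the 12 largest rises included rbbA, a ribosome-associated ATPase (1.28, SE 0.11), ycaC, a putative hydrolase (1.07, SE 0.07), and nrdH and nrdI, partners of a ribonucleotide reductase (1.21, SE 0.13, and 1.20, SE 0.14). The parental means of nrdH and nrdI were low, at 5.00 and 4.80. The fall of ddg, now named lpxP, a cold-induced acyltransferase of lipid A synthesis, was -1.12 (SE 0.11). For all 24 of the largest rises and falls besides recA, the 3 deletion arrays lay beyond the 3 parental ones, as for 46.7% of tested genes where chance gives 10%. Row of the slide overlapped with strain: with row as a block, which sets deletion array 1 against the parental arrays, 607 genes passed (320 higher, 287 lower), 515 of them among the 996. Each difference given below with slide row as a block is thus that of deletion array 1, not a mean over the 3 deletion cultures. Leaving out parental array 2 left 649 genes and leaving out parental array 3 left 650.

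Genes of the SOS regulon, the DNA damage response under LexA control, fell as a group. Of 29 measured members besides recA, 22 fell, 0 rose and 7 did not pass, and 25 fell when adjusted over the list alone. The repair gene recN fell by 2.38 (from 7.76 ± 0.12 to 5.38 ± 0.09, SD, n = 3), a 5.21-fold difference with adjusted p = 2.39e-06. sulA, the inhibitor of cell division, fell by 1.39 (SE 0.07), and yebG, a gene of unknown function under LexA control, fell by 1.11 (SE 0.07). dinI, a modulator of RecA filaments, umuD, part of DNA polymerase V, and lexA itself differed by -0.89 (SE 0.07), -0.86 (SE 0.12) and -0.73 (SE 0.07). The umuD signal was dim on deletion arrays 2 and 3 (4.11 and 4.34), so the size of its fall is less certain. recX, the gene next to recA and an inhibitor of RecA, fell by 0.41 (SE 0.09), a call that ended with slide row as a block (-0.31, SE 0.12, adjusted p = 0.118). The mean shift of the list was -0.56 (camera adjusted p = 7.31e-11; adjusted p = 0.127 with an estimated correlation). With slide row as a block the shift was -0.54.

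**Figure D1:**
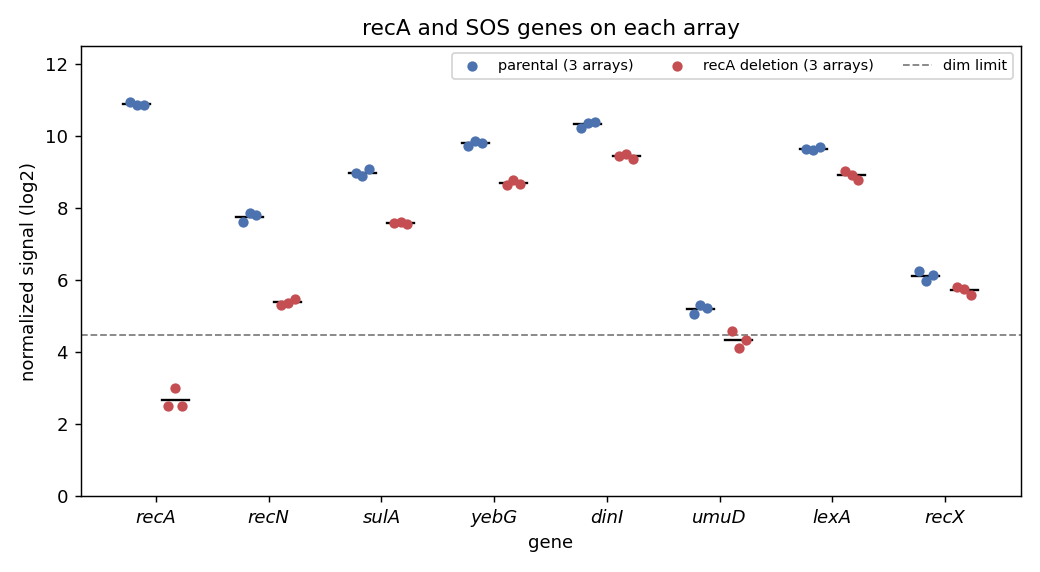
Normalized signal (log2, y axis) of recA and 7 SOS genes (x axis) on each array; points are single arrays, black bars the mean of the 3 arrays of a strain, and the dashed line the limit below which a signal was dim. The 3 deletion arrays lay below the 3 parental arrays for each gene. recA was dim on all 3 deletion arrays and umuD on deletion arrays 2 and 3.

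Nitrogen limitation genes fell as a group. Of 20 measured, 15 fell, 1 rose and 4 did not pass; adjusted over the list alone, 15 fell and 2 rose. glnK was 7.70-fold lower and amtB, the ammonium channel encoded with it, 3.59-fold lower (-1.85, SE 0.10). nac, a regulator of nitrogen assimilation, was 4.29-fold lower (-2.10, SE 0.09), and glnG, the response regulator NtrC of nitrogen control, 2.72-fold lower (-1.45, SE 0.07). Its partner kinase gene glnL differed by -1.44 (SE 0.07), and glnA, glutamine synthetase, by -1.12 (from 14.28 ± 0.15 to 13.17 ± 0.07, SD, n = 3). cbl, a regulator of sulfonate use, was the member that rose (0.47, SE 0.10); with slide row as a block the difference was smaller, 0.30 (SE 0.11), and the call was lost (adjusted p = 0.102). The mean of the list was -0.81 (camera adjusted p = 1.59e-07; adjusted p = 0.245 with an estimated correlation), and -0.84 with slide row as a block. This was the largest mean of the lists tested, but without the filter on dim genes it was -0.61, smaller in size than the heat shock mean of 0.68.

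Heat shock and cold shock genes moved in opposite directions. Of 19 heat shock chaperone and protease genes, 16 rose, 0 fell and 3 did not pass, with the same 16 adjusted over the list alone. ibpB rose 3.87-fold, its partner ibpA 2.52-fold (1.33, SE 0.08), clpB, a disaggregase, 2.43-fold (1.28, SE 0.10), and htpG, the Hsp90 homologue, 2.01-fold (1.01, SE 0.08). The list mean was 0.68 (camera adjusted p = 2.27e-11; adjusted p = 0.213 with an estimated correlation), and 0.72 with slide row as a block. Of 9 measured cold shock genes, 5 fell, 1 rose and 3 did not pass; adjusted over the list alone, 5 fell and 2 rose. The RNA chaperone genes cspG, cspA and cspE differed by -1.39 (SE 0.11), -1.08 (SE 0.11) and -0.66 (SE 0.07); they are related in sequence, so cross-hybridisation between them is uncertain. deaD, an RNA helicase of ribosome assembly in the cold, differed by -1.10 (SE 0.07). The member that rose was yfiA, known to inactivate ribosomes (0.45, SE 0.06). The cold shock mean was -0.47 (camera adjusted p = 0.0166; adjusted p = 0.294 with an estimated correlation) and stayed at -0.47 with slide row as a block.

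General stress genes rose in the deletion strain. Of 30 measured genes of the RpoS (stationary phase sigma factor) list, 28 rose, 0 fell and 2 did not pass, and 28 rose when adjusted over the list alone. Examples were yiaG, a predicted regulator (1.37, SE 0.07), dps, a DNA-binding protein that protects against oxidants (1.01, SE 0.12), wrbA, a quinone reductase (0.97, SE 0.08), and yhjG (0.93, SE 0.08). The list mean was 0.61 (camera adjusted p = 5.95e-15; adjusted p = 0.153 with an estimated correlation). Of 12 measured acid resistance genes, 10 rose, 1 fell and 1 did not pass, with the same counts of 10 and 1 adjusted over the list alone. hdeD rose by 1.32 (SE 0.12), the periplasmic acid chaperone genes hdeA and hdeB by 1.05 (SE 0.10) and 0.98 (SE 0.08), and gadB, glutamate decarboxylase, by 0.99 (SE 0.12), though gadB has the near-identical copy gadA and the values of the pair are uncertain. asr, an acid-induced periplasmic protein, was the member that fell (-0.52, SE 0.11; -0.80, SE 0.08, with slide row as a block). The acid resistance mean was 0.62 (camera adjusted p = 5.38e-06; adjusted p = 0.294 with an estimated correlation). With slide row as a block the means were 0.54 for the RpoS list and 0.50 for the acid resistance list.

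Among fimbriae, curli and biofilm genes 19 of 26 were dim in both strains, and of 7 measured 5 rose, 0 fell and 2 did not pass, also when adjusted over the list alone. The 5 were curli genes, among them csgF (1.25, SE 0.11), csgE (1.00, SE 0.15), csgD, the curli regulator (0.88, SE 0.11), and csgG, the curli secretion channel (0.61, SE 0.10). The list mean was 0.63 (camera adjusted p = 0.00033; adjusted p = 0.153 with an estimated correlation). Without the filter on dim genes the mean was 0.18 and the call was lost (adjusted p = 0.064).

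Several nutrient and biosynthesis lists were also higher. Of 20 sulfur assimilation genes, 15 rose and 5 did not pass, led by sbp, the sulfate-binding protein (1.22, SE 0.11), cysP, the thiosulfate-binding protein (0.70, SE 0.10), cysD, a sulfate adenylyltransferase subunit (0.68, SE 0.13), and tcyP, a cystine importer listed as ydjN (0.67, SE 0.07). The call of cysD was lost with slide row as a block, where the difference was 0.44 (SE 0.15, adjusted p = 0.091). Of 13 methionine biosynthesis genes 9 rose and 4 did not pass, with the regulator metR at 0.735 (SE 0.08) and metA at 0.69 (SE 0.08). Calls of metE (0.61) and metL (0.60) were lost with slide row as a block (adjusted p = 0.062 and 0.094). Branched-chain amino acid genes gave 11 rises among 22, with ilvC at 0.61 (SE 0.09). Calls of leuB (0.52), leuA (0.47) and ilvG (0.45) were lost with slide row as a block (adjusted p = 0.095, 0.103 and 0.112). Phosphate starvation genes gave 7 rises among 16, all of the other 9 failing to pass. In the latter list pstS, the phosphate-binding protein, rose by 1.08 (SE 0.08) and its transporter genes pstB and pstA by 0.82 (SE 0.07) and 0.66 (SE 0.07). Oxidative stress genes of the SoxRS and OxyR regulons gave 9 rises among 25, including soxS (0.70, SE 0.10), sufB (0.68, SE 0.12; 0.41, SE 0.11, with slide row as a block) and katG, a catalase (0.62, SE 0.06), besides dps. No member of these 5 lists fell. Adjusted over each list alone, 15, 9, 12, 9 and 9 rose. Camera adjusted p, in the order sulfur, methionine, branched-chain, phosphate and oxidative, was 2.10e-06, 9.27e-06, 5.80e-05, 6.15e-05 and 0.00023. In the same order the adjusted p with an estimated correlation was 0.301, 0.127, 0.322, 0.127 and 0.294. The list means were 0.48, 0.40, 0.26, 0.37 and 0.25. With slide row as a block they were 0.36, 0.39, 0.18, 0.36 and 0.18, the last with a camera adjusted p of 0.025. Without the filter on dim genes the phosphate starvation mean was 0.21 (adjusted p = 0.0015).

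**Figure D2:**
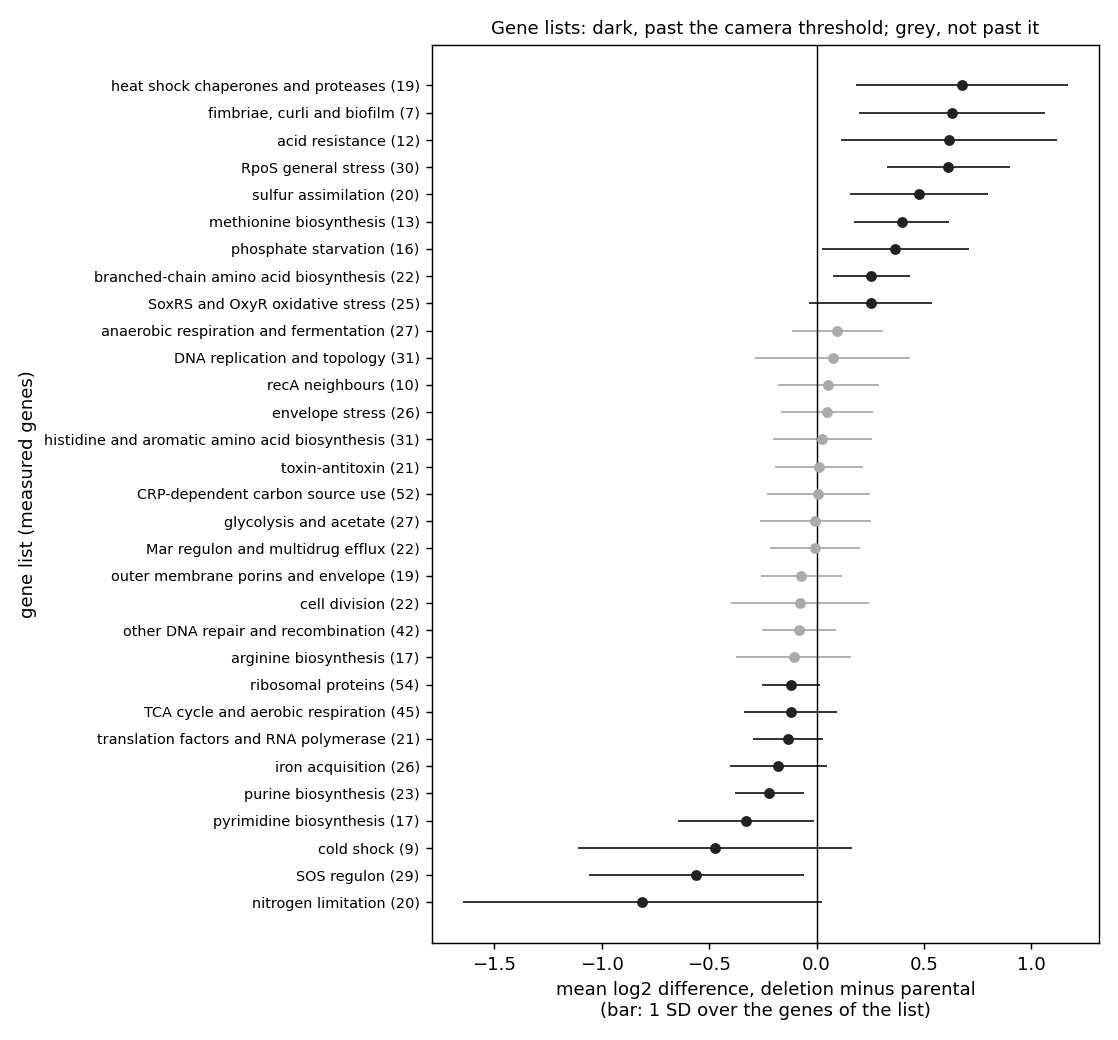
Mean log2 difference (x axis, deletion minus parental) of the 31 gene lists tested (y axis, with the number of measured genes); points are list means, bars 1 SD over the genes of the list, dark points lists past the camera threshold and grey points the others. The means of the dark lists ran from -0.81 for nitrogen limitation to 0.68 for heat shock.

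Nucleotide synthesis genes were lower in the deletion strain. Of 17 pyrimidine genes 10 fell, 1 rose and 6 did not pass (12 and 2 adjusted over the list alone), with codB, the cytosine importer, at -0.69 (SE 0.12), the carbamoyl phosphate synthetase genes carB and carA at -0.68 (SE 0.12) and -0.61 (SE 0.11), and pyrI at -0.60 (SE 0.10). The rise was that of udp, a uridine phosphorylase of the salvage route (0.44, SE 0.07). Of 23 purine genes 12 fell, 0 rose and 11 did not pass (12 falls adjusted over the list alone), among them prs, listed as prsA (-0.42, SE 0.07), and purK (-0.41, SE 0.07). The largest fall in the purine list was that of codA, cytosine deaminase (-0.56, SE 0.07), which is also a member of the pyrimidine list. The pyrimidine and purine means were -0.33 and -0.22. Camera adjusted p was 0.00056 for pyrimidine genes (adjusted p = 0.322 with an estimated correlation) and 0.00011 for purine genes (adjusted p = 0.294 with an estimated correlation).

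Iron, respiration and translation lists had smaller falls. Among 26 iron acquisition genes 11 fell, 1 rose and 14 did not pass (13 and 1 adjusted over the list alone): the enterobactin genes fepG and entS, the latter listed as ybdA, differed by -0.50 (SE 0.07) and -0.49 (SE 0.07), and sufA, of iron-sulfur cluster assembly, rose by 0.57 (SE 0.07). Among 45 genes of the TCA cycle and aerobic respiration 15 fell, 1 rose and 29 did not pass (15 and 2 adjusted over the list alone). The succinate dehydrogenase genes sdhB, sdhA and sdhD differed by -0.58 (SE 0.09), -0.55 (SE 0.09) and -0.43 (SE 0.07), and aceB, malate synthase, rose by 0.35 (SE 0.07). With slide row as a block the aceB difference was 0.29 with a wider error (SE 0.09), and its call was lost (adjusted p = 0.069). Of 54 ribosomal protein genes 10 fell, 0 rose and 44 did not pass (8 falls adjusted over the list alone), with rplI at -0.41 (SE 0.07) and rplS at -0.35 (SE 0.06). The largest fall, of rplQ (-0.42, SE 0.11), lost its call with slide row as a block (-0.24, SE 0.14, adjusted p = 0.257). Of 21 translation factor and RNA polymerase genes 7 fell, 0 rose and 14 did not pass (7 falls adjusted over the list alone), with the initiation factor gene infB at -0.47 (SE 0.07). The means of these 4 lists were -0.18, -0.12, -0.12 and -0.13. Camera adjusted p was 0.0036, 0.0056, 0.0027 and 0.047 in that order. The adjusted p with an estimated correlation was 0.153, 0.373, 0.322 and 0.373. With slide row as a block the TCA cycle and respiration mean was -0.18. The translation factor call, close to the threshold, was lost without parental array 3 (mean -0.12, adjusted p = 0.079) and without deletion array 1 (mean -0.11, adjusted p = 0.144), while the mean stayed near its size with all arrays.

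DNA repair, replication and cell division lists other than the SOS regulon did not pass the camera test. Of 42 other repair and recombination genes 10 fell, 1 rose and 31 did not pass, with nth, endonuclease III, at -0.58 (SE 0.07); the list mean was -0.08 (camera adjusted p = 0.136). Adjusted over the list alone, 9 fell and 1 rose. Of 31 replication and topology genes 7 rose, 3 fell and 21 did not pass, also adjusted over the list alone. The largest members were dps and the ribonucleotide reductase genes nrdA and nrdB, which rose by 0.98 (SE 0.08) and 0.97 (SE 0.07). The mean was 0.08 (camera adjusted p = 0.495). Of 22 cell division genes 1 rose, 3 fell and 18 did not pass, with sulA the largest member (mean -0.08, median 0.0059, camera adjusted p = 0.609), and the counts adjusted over the list alone were the same. Of 10 measured neighbours of recA 1 rose, 1 fell and 8 did not pass, likewise adjusted over the list alone: pncC, listed as ygaD, rose by 0.50 (SE 0.10) and recX fell. The neighbours' mean was 0.05 (camera adjusted p = 0.504).

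Multidrug efflux and envelope genes, which bear on entry and export of compounds, did not pass the camera test as lists. Of 22 Mar regulon and efflux genes 2 rose, 2 fell and 18 did not pass, and 1 rose and 1 fell when adjusted over the list alone; soxS was the largest member, and mdfA, a multidrug exporter listed as cmr, differed by -0.38 (SE 0.08). Of 19 porin and outer envelope genes 1 rose, 3 fell and 15 did not pass (0 and 2 adjusted over the list alone), with tolR and tolQ at -0.42 (SE 0.08) and -0.40 (SE 0.07). The largest fall was that of tolA (-0.45, SE 0.15), where the arrays of the strains overlapped. Of 26 envelope stress genes 6 rose, 2 fell and 18 did not pass, also adjusted over the list alone, with the protease gene degP at 0.56 (SE 0.07) and pspA at 0.45 (SE 0.08). The list means were -0.0061, -0.07 and 0.05, with camera adjusted p of 0.860, 0.504 and 0.468.

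In the remaining metabolic lists, calls went both ways or were few. Arginine genes gave 0 rises and 3 falls among 17, carB and carA being the largest. Histidine and aromatic amino acid genes gave 5 rises and 5 falls among 31, with trpD at 0.52 (SE 0.08). For glycolysis and acetate, 6 of 27 genes rose and 3 fell, fbaB reaching 0.63 (SE 0.10). Of 27 anaerobic respiration and fermentation genes 6 rose and 0 fell, with nrdD, the anaerobic ribonucleotide reductase, at 0.54 (SE 0.09; 0.36, SE 0.09, with slide row as a block). CRP-dependent carbon source genes gave 7 rises and 8 falls among 52, including xylB (0.65, SE 0.07) and crp itself (0.46, SE 0.06), and toxin-antitoxin genes 3 and 3 among 21. Adjusted over each list alone, rises and falls numbered 0 and 3, 5 and 6, 6 and 6, 5 and 0, 7 and 8, and 3 and 3 in the same order. The means were -0.11, 0.03, -0.0050, 0.10, 0.0075 and 0.01, with camera adjusted p of 0.410, 0.580, 0.963, 0.078, 0.740 and 0.860. For glycolysis the median was -0.10 with camera's direction upward, and for toxin-antitoxin genes the median was -0.0066. The anaerobic list passed without parental array 3 (adjusted p = 0.049), without deletion array 1 (adjusted p = 0.016) and without the dim filter (adjusted p = 0.035). Its mean shrank to 0.04 with slide row as a block (camera adjusted p = 0.530). It was 0.06 without deletion array 3 (adjusted p = 0.297) and 0.07 without parental array 2 (adjusted p = 0.189).

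Of 51 flagella and chemotaxis genes 47 were dim in both strains and 1 was measured, which did not pass. Of 129 table entries for insertion sequences and cryptic prophages, elements that reduced-genome strains of this kind lack by design, 127 were dim in both strains. The 2 measured were ychG (-0.28, SE 0.11, adjusted p = 0.078) and ymfR (0.12, SE 0.10, adjusted p = 0.384). In total 18 of the 31 lists tested passed the camera threshold, 9 in each direction, 0 did so with an estimated correlation, and 20 did so by fry: the same 18 with the other DNA repair and the replication lists. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes.

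**Figure D3:**
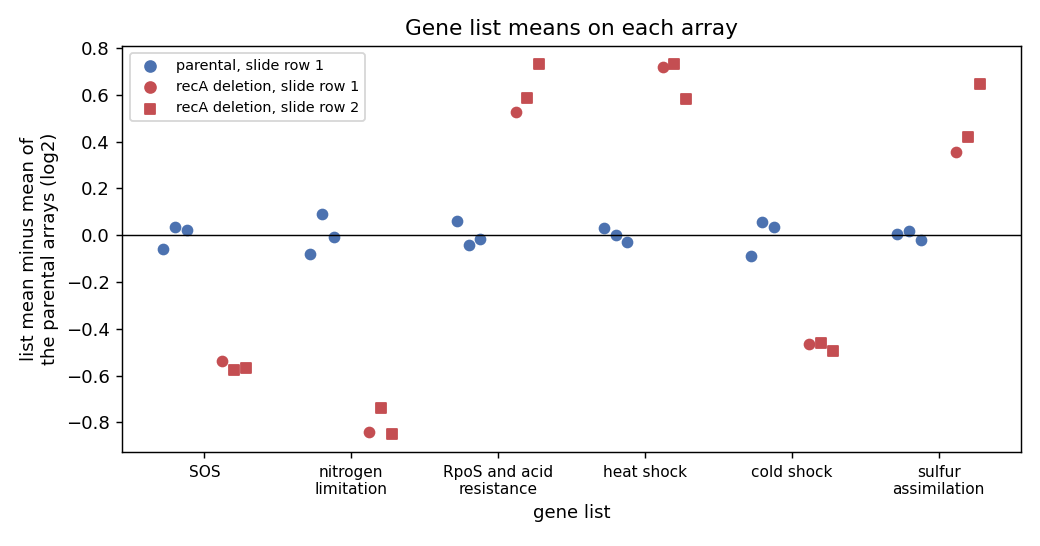
Mean log2 signal of 6 gene lists (x axis) on each array after subtracting the mean of the 3 parental arrays (y axis, log2); colour gives the strain and marker shape the row of the slide. For each list the 3 deletion arrays lay on one side of the 3 parental arrays, and deletion array 1 lay at -0.54 for SOS genes and -0.84 for nitrogen limitation genes. For sulfur assimilation genes deletion array 1 lay at 0.36, below deletion arrays 2 and 3 at 0.42 and 0.65.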

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

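The gene-level dim filters and the spike-in scaling were chosen after the data were seen, and the other settings before. The mean of a gene's probes could not be run, since no probe is paired with a gene, and changes of background correction or scaling were run per probe. In the settings that refitted recA it kept its direction and its call, with the size of the fall known only as a bound; the filter to genes above the dim limit on all 6 arrays removed it, and the plain t-test and the minimum difference were run for counts only. The SOS shift stayed between -0.59 and -0.51 and past the threshold except with an estimated inter-gene correlation (-0.56, adjusted p = 0.127). That setting also took the count of lists past the threshold to 0, while each other setting left 18 to 20 lists. Estimated correlations were -0.0082, 0.0003 and 0.0088 for the methionine, iron and phosphate lists, at or below the preset 0.01. Their calls were lost all the same, so that setting changes more than the correlation. The other called lists had estimates above 0.01. Of 221 alternative values of the other 17 called lists, 201 kept direction and call, 20 lost the call and 0 changed direction. Of 1483 alternative values of 135 called named genes, 136 lost the call and 0 changed direction. Those lost calls numbered 36 with slide row as a block, 18 without parental array 3, 17 without parental array 2, and 17 without the dim filter, where more genes were tested.

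With 996 genes (494 higher, 502 lower) as the reference, slide row as a block gave 607 (320 and 287), a plain t-test 610 (316 and 294), and a minimum log2 difference of 1 left 30 (15 and 15). Leaving out 1 array in turn, so that fewer arrays entered each fit, gave 649 to 931 genes, 358 to 474 higher and 285 to 457 lower. The lowest values came without parental array 2 (649, 291 lower) and parental array 3 (650, 285 lower). Without parental array 1 the count was 806, so the number of arrays does not explain which counts were lowest. Without the dim filter 328 genes were lower. Numbers of replicates did not pair the samples: the correlations of deviations for numbers 1, 2 and 3 were -0.06, -0.0040 and 0.05. The replicate block gave 874 genes and 18 lists.

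Per probe, 6518 of 37826 kept probes passed (17.2%, 58.4% of them higher). Median centring gave 7452 with 39.3% higher, so the balance of rises and falls depended on the scaling; it shifted the median difference by -0.07, more than the other scalings. That size is below the mean of each called list, the smallest being -0.12. Spike-in scaling gave 2993, no dim filter 1564, slide row as a block 1896, a plain t-test 2694, a minimum log2 difference of 1 left 556, and leaving out arrays 2974 to 4806 (parental array 3 lowest, then 3352 without parental array 2, 4177 without deletion array 3 and 4189 without deletion array 2). The replicate block gave 4752 probes. Apart from the array left out and the numbers of genes tested, the cause of these differences was not tested.

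Direction changed only in uncalled values near 0. These were the Mar and efflux list without the dim filter (0.010) and over arrays left out (-0.024 to 0.017), the histidine and aromatic list (-0.019) and the CRP list (-0.010) with slide row as a block, and nrdG with slide row as a block (-0.11). With arrays left out in turn, the ranges were -0.019 to 0.019 for glycolysis, -0.015 to 0.053 for toxin-antitoxin genes, -0.0080 to 0.050 for histidine and aromatic genes and -0.013 to 0.020 for CRP genes. The 1182 genes dim in both strains may include genes that the reduced genome lacks as well as genes with low signal. No MDS42 genome was used to tell these apart. Values given without the dim filter take in both kinds, so a smaller mean there need not show a weaker response.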

Other observations

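The gene groups in this first paragraph and the probe set in the next were picked out after their values were seen. The tests in the later paragraphs were written before their own results were seen, but after a first look at the largest gene differences, which had shown the patterns they weigh. Ribonucleotide reductase genes, which make the precursors of DNA, were higher in the deletion strain: 7 of 8 measured rose. Besides nrdA, nrdB and nrdD, these were the manganese-dependent enzyme's genes nrdE (0.79, SE 0.16) and nrdF (0.90, SE 0.10) with their partners nrdH (1.21, SE 0.13) and nrdI (1.20, SE 0.14), while nrdG differed by 0.17 (adjusted p = 0.301). The call of nrdE was lost with slide row as a block (0.50, SE 0.18, adjusted p = 0.099). All 4 measured genes of glutamate and aspartate uptake fell, gltL by the largest amount (-0.82, SE 0.09). These 4 are also members of the nitrogen limitation list, so they are not a separate result. Of 6 glycogen genes 4 rose and 0 fell, with glgX at 0.83 (SE 0.16), a call lost with slide row as a block (0.67, SE 0.22, adjusted p = 0.084). Of 5 measured RNA helicase and cold ribosome factor genes, 3 fell: deaD, rhlE (-0.67, SE 0.07) and rbfA (-0.52, SE 0.07). Of these, deaD and rbfA are also members of the cold shock list.

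Per probe, the scanner signals held an isolated set of large falls. Of 36256 numbered or catalogue probes well above background on all parental arrays, 12 consecutively numbered probes fell by more than 6 on the log2 scale, 11 of them to a level not well above background on any deletion array; the next largest fall of any probe was -3.17. The scanner files pair no probe with a gene. Across the array, 28 probes were well above background on all parental and no deletion arrays, and 248 on all deletion and no parental arrays. The share of all probes well above background was also higher on the deletion arrays (63.9%, 69.5% and 65.6%) than on the parental ones (62.4% to 63.6%). These counts therefore do not separate transcripts gained from a difference in detection.

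The number of genes called was weighed first. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; the real split called 996 genes and the highest of the others 0, so 1 split reached the real count. The authors' quantile normalization as the whole source of the calls is argued against by the scanner signals: with 75th percentile scaling only, 17.2% of kept probes passed the threshold, and quantile normalization in its place gave 15.6%. The bound fixed beforehand, 15.9%, was derived from the share of genes called and applied to probes, which are unlike units. It was passed narrowly and not under every scaling. Below it lay cyclic loess with 15.8%, quantile normalization itself and spike-in scaling with 7.9%. A part of the calls may therefore still depend on the scaling. With slide row as a block 607 genes passed, but the median SE also widened from 0.08 to 0.10, so that count does not separate row from lost precision.

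Lower nitrogen genes together with higher RpoS and acid resistance genes formed the pattern weighed next. Row of the slide as the whole source is argued against by deletion array 1, which shared its row with the parental arrays. In both the nitrogen list and the pooled RpoS and acid lists its shift was at least 80.3% of that of deletion arrays 2 and 3. This rests on 1 deletion array, the same one that the row block uses. For acid resistance genes alone the shift was 0.50 on deletion array 1 and 0.68 on deletion arrays 2 and 3. A part that follows row therefore stays open. Deletion cultures nearer to stationary phase at harvest remain a candidate explanation for the higher RpoS and acid resistance genes. Ribosomal protein genes, which fall as growth slows, had a mean difference of -0.12, the direction that explanation needs. The ribosomal protein test bears on growth only. It does not show that such cultures would have lower nitrogen genes, whose list mean was -0.81. That test rested on a small shift whose adjusted p was 0.322 with an estimated correlation, and growth was not measured in the files. Culture state and an effect of the deletion itself both stay open.

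Heat shock genes higher and cold shock genes lower made up the third pattern. A single array does not account for it: with 1 array left out in turn, the means of both lists kept at least 94.2% of their values. A distortion that follows signal level is also argued against, as the heat shock mean lay at percentile 100 and the cold shock mean at percentile 0 of 10000 random lists matched on signal. A difference in temperature between the cultures or at harvest may be another explanation; the labels give 34 °C for both strains, and it was not tested. An effect of the recA deletion stays open as a hypothesis.

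A further hypothesis was that calls follow shared transcripts rather than single probes. Of 985 called genes placed on the reference chromosome, 52.8% had a neighbour called in the same direction, against a mean of 26.5% and a highest value of 33.0% in 1000 shuffles of the tested genes. This is consistent with calls that follow transcription units, although regional effects of other kinds on the chromosome were not tested.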
